A study of Magallana angulata with 3 samples.

How the data were processed

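Messenger RNA of adductor muscle, the muscle that closes the shell, was profiled in 3 libraries of the Fujian oyster (Magallana angulata). The labels describe 2 libraries as diploid, named DF and DM, and 1 as triploid, named T. They do not say what the letters F and M stand for, nor how many animals went into a library. Per the labels' protocols, the diploids came from crosses of diploid parents and the triploids from the same parents by chemical retention of the second polar body, and all animals were kept for a year under equal temperature and food. Poly(A) RNA was selected with oligo(dT), made into libraries with an Illumina digital gene expression kit and sequenced on an Illumina instrument, per the labels' protocols. TopHat is named in the submitters' processing notes, without its version. The counting program, the genome build and the gene annotation are not given in the sources used here.

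The authors deposited 1 table per library with an RPKM value (reads scaled by gene length and by the read total of the library) for each of 28027 gene identifiers. The unit is given in the names of the deposited files and was checked on the values. The authors' RPKM values divide by gene length and by a read total, so that a few very abundant genes in 1 library lower every other gene there. The identifiers carry no gene names, and 0 of the 28027 occur in the reference gene table of this species that was used. Genes are therefore given by identifier, with no function or position, and the lists of muscle, metabolic and cell type genes that had been fixed as product names were not used here.

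The depth was recovered from the deposited RPKM values themselves, which have 10 significant digits. The commonest ratio between the values of 2 libraries, which is that of genes with equal reads, gave the ratio of their totals. The spacing of low values then gave the totals, under the assumption that lengths are coding lengths, in multiples of 3 nt. Of several candidate totals, the set whose recovered reads came closest to the totals without passing them was taken. The totals came out within 0.0035 of whole numbers in all 3 libraries, at 1805591 reads in DF, 2057805 in DM and 2137859 in T. Of 19931 genes above 0 in any library, 100% then had whole reads in every library, within 0.001 of a read (or a relative error near the rounding of the values for the most abundant genes). Whole reads alone separate the candidate totals little, since the candidates not chosen left between 0 and 109 genes without them. The reads summed to between 97.45% and 98.02% of the totals. A common factor of a gene's reads and length cannot be seen, so recovered reads are a lower limit. In simulated libraries with the same totals over 19931 genes, the totals were recovered without error, 92.9% of genes had exactly the simulated reads, 0 had more, and at most 97.83% of reads were recovered. One read in a gene of 1 kb is worth 0.554 RPKM in DF, 0.486 in DM and 0.468 in T. Intervals from reads are 95% exact (Poisson for a value, Clopper-Pearson for a ratio). They cover counting error of reads only, not differences between animals or library preparations. As intervals for molecules they can be too narrow, since copies made by amplification are not separate molecules.

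Each label has 1 library, so there is no replicate error and the main comparisons carry no p-value. Genes with a mean of at least 1 RPKM over the 3 libraries (14402) were compared on log2(RPKM + 1), a scale that understates the change of low genes. A gene was called higher or lower by a size rule, a difference of at least 2-fold. For the triploid, the rule had to hold against DF and against DM on the same side. The same rule with DF or DM as the library set against the other 2 served as the yardstick. Libraries that differ by counting error only were simulated 100 times from the pooled reads. Spread between libraries was measured as the median absolute deviation of log2 differences over 3351 genes with a mean of at least 50 reads, with 95% bootstrap intervals over genes from 1000 draws. The size rule was tested on simulated data for the triploid comparison, with 200 of 19931 genes changed: it called 100% of genes changed 8-fold, 92.1% of those changed 4-fold and 19.1% of those changed 2-fold. The changed genes were drawn only from genes above a minimum of pooled reads, so these shares do not cover genes with fewer reads. The rule also called 181 unchanged genes higher and 295 lower, against 6 and 16 when the 95% counting interval of the ratio of reads had to leave out 1 as well. Apart from the changed genes, these simulated libraries differed by counting error only. The real libraries also differed by overall shifts and a wider spread, so these shares and counts may not carry over to them.

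The size rule, the alternatives not marked as added, and the rule for genes named in the text were fixed before the data were examined. Where identifiers have no names, that rule allows at most 2 identifiers per direction. These are the genes with a mean of at least 10 RPKM past the limit that have the largest difference of DM from DF or, for the triploid, the largest value of the smaller of its differences from DF and DM. Other identifiers are marked as chosen after their values were seen. The alternatives tried were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 RPKM, other scalings (median of ratios, trimmed mean, equal sums with and without the 20 most abundant genes), fold limits of 1.5 and 4, the counting interval of the reads, each diploid library alone, and limma with DF and DM as 2 diploid libraries. Reads scaled to the total without gene length, and the counting interval together with median-of-ratios scaling, were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and limma 3.58.1 in R 4.3.3.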

Results

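The data comprise 3 adductor muscle libraries, 1 for each of the labels DF (diploid), DM (diploid) and T (triploid). The read totals behind the RPKM values were 1805591 in DF, 2057805 in DM and 2137859 in T. RPKM was above 0 for 17246 genes in DF, 15969 in DM and 17467 in T, and 13987 genes were above 0 in all 3. A single gene, CGI_10018876, was the most abundant in every library. It took 17.55% of the reads in DF, 33.84% in DM and 23.90% in T. This gene, named after its values were seen, was 1.93-fold higher in DM than in DF (95% counting interval 1.92 to 1.94). The 20 most abundant genes together took 35.29%, 52.36% and 41.77% of the reads in DF, DM and T. None of the differences below has a replicate check, since each label has 1 library.

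The series was set up to compare muscle gene expression between diploid and triploid oysters. Across 14402 genes, 897 were at least 2-fold higher in the triploid than in both diploid libraries, and 394 were at least 2-fold lower than in both. Of these, 596 higher and 280 lower genes had a mean between 1 and 10 RPKM, as did 8218 of all genes compared. Among the 138 genes with a mean of at least 1000 RPKM, 3 were higher and 4 lower. When the 95% counting interval of the ratio of reads also had to leave out 1 against each diploid library, 571 genes were higher and 117 were lower, of which 282 and 34 had a mean between 1 and 10 RPKM.

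Of the higher genes named by the rule, CGI_10003417 had 653 RPKM in the triploid (95% counting interval 629 to 679), 18.9 in DF (14.6 to 24.1) and 15.1 in DM (11.5 to 19.4). It rested on 2661 reads in T, 65 in DF and 59 in DM, and was 34.6-fold higher than in DF (27.0 to 44.9) and 43.4-fold higher than in DM (33.5 to 57.2). The other, CGI_10013287, had 73.6 RPKM in T from 17 reads and 0 reads in both diploid libraries. With a floor of 3 reads in place of 0, it was 4.79-fold higher than in DF and 5.45-fold higher than in DM, and the lower limits of the 95% counting intervals were 3.49 and 3.97. Among the lower genes, CGI_10003466 had 3.29 RPKM in T (3 reads), 29.9 in DF (23 reads) and 27.4 in DM (24 reads). Its level in DF was 9.08 times that in T (95% counting interval 2.74 to 47.2), and its level in DM 8.31 times (2.52 to 43.1). CGI_10002961 had 0 reads in T, 9 in DF (19.6 RPKM) and 6 in DM (11.4 RPKM). With the same floor in place of 0, DF was 3.55-fold and DM 2.08-fold higher. The lower limits of the 95% counting intervals were 2.34 and 1.22, so that a difference under 2-fold from DM was not excluded at this depth.

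The counts were first set against counting error alone, which leaves out differences between animals and between library preparations. The simulated libraries gave a mean of 167.5 higher genes (at most 201 in 100 draws) and 317.2 lower genes (at most 353). The 897 higher genes lay above all 100 draws, as did the 394 lower genes by a smaller distance. With the counting interval required, the simulated libraries gave at most 19 higher and 21 lower genes. Both comparisons share the triploid library. Independent lists of the sizes found (1450 and 3656 higher, 2680 and 694 lower) would share 368.1 higher and 129.1 lower genes. These lists are not independent, however. With counting error alone, simulated higher lists with means of 708.7 and 641.0 genes shared a mean of 167.5. Simulated lower lists with means of 658.0 and 628.5 genes shared 317.2. The shared library thus produces overlap by itself, and the excess over independent lists is no measure of a ploidy difference.

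By the same rule, each diploid library stood apart from the other 2 in more genes than the triploid did. DF was higher than both DM and T in 2007 genes and lower in 582. DM was higher than both others in 195 genes and lower in 2320. With the counting interval required on the deposited scale, DF had 1443 higher and 263 lower genes, against at most 19 and 32 in simulated libraries, and DM had 107 and 1344, against at most 14 and 29. These splits depended on the scaling. After median-of-ratios scaling, T was higher than both diploids in 821 genes and lower in 499, DF was higher than both others in 1092 and lower in 886, and DM was higher in 681 and lower in 1159. With this scaling and the counting interval together, T had 499 higher and 147 lower genes, DF 708 and 465, and DM 443 and 397. Of the 897 and 394 genes of the deposited scale, 719 and 350 were among those called in the triploid after median-of-ratios scaling.

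**Figure D1:**
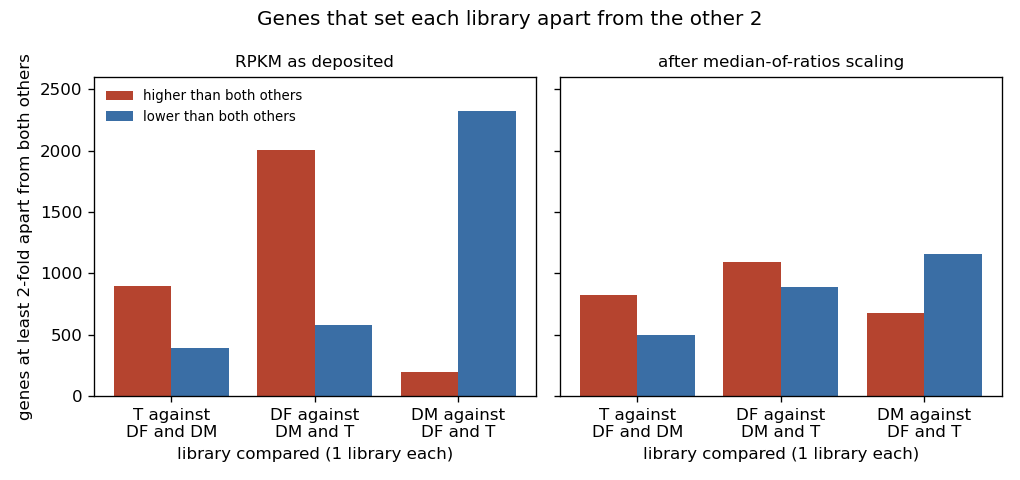
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) in 1 library than in both others, for the triploid library T and the diploid libraries DF and DM, with RPKM as deposited (left) and after median-of-ratios scaling (right). The triploid has 897 higher and 394 lower genes on the left and 821 and 499 on the right, fewer in total than either diploid library in both panels.

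Pair by pair, 1450 genes were higher and 2680 lower in T than in DF, while 3656 were higher and 694 lower in T than in DM. Simulated counting error gave at most 783 and 713 genes for the first pair and at most 694 and 703 for the second. The 694 genes lower in T than in DM were thus no more than the simulated libraries reached. After median-of-ratios scaling the split was 1780 higher and 1827 lower against DF, and 2252 higher and 1448 lower against DM. Higher genes made up 35.1% of the calls against DF as deposited and 49.3% after scaling, and 84.0% and 60.9% against DM. With the counting interval required on the deposited scale, the counts were 847 higher and 1848 lower against DF, and 2407 higher and 314 lower against DM, where simulated libraries reached at most 115 and 108, and 106 and 107. With this interval and median-of-ratios scaling together, they were 1146 higher and 1132 lower against DF, and 1152 higher and 846 lower against DM.

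The diploid libraries DM and DF were compared with each other as the measure of difference without a change of ploidy. Their labels differ by the letters F and M, so this measure also holds whatever those letters stand for. The label T carries neither letter, so the triploid library cannot be matched to DF or DM in this respect. In DM, 801 genes were higher and 5328 lower than in DF, against at most 788 and 735 in simulated libraries that differed by counting error. With the counting interval required, 402 were higher and 3955 lower, against at most 115 and 117. After median-of-ratios scaling, 1931 genes were higher and 2648 lower, and the share of higher genes among the calls went from 13.1% to 42.2%. With this scaling and the counting interval together, 1323 genes were higher and 1510 lower. The median log2 difference of DM from DF over 3351 genes with a mean of at least 50 reads was -0.52 as deposited and 0.25 after median-of-ratios scaling. Under the other scalings it ranged from -0.42 (equal sums of RPKM) to 0.29 (trimmed mean). Equal sums without the 20 most abundant genes gave -0.03, so its sign depended on the scaling. For T the median was -0.24 against DF and 0.37 against DM as deposited, and 0.05 and -0.12 after median-of-ratios scaling.

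Some genes were abundant in one diploid library and near 0 in the other. CGI_10015188 had 2.40 RPKM in DF (3 reads), 1898 in DM (2707 reads) and 9714 in T (14391 reads). It was 792-fold higher in DM than in DF (95% counting interval 271 to 3840). CGI_10021396 had 0 reads in DF, 864 RPKM in DM from 80 reads and 3856 RPKM in T from 371 reads. With a floor of 3 reads in place of 0, CGI_10021396 was 23.4-fold higher in DM than in DF (lower limit of the 95% counting interval 18.6). Its recovered coding length is 45 nt, and its reads and length can both be larger by a common factor. In the other direction, CGI_10023461 had 537 RPKM in DF (1225 reads), 1.92 in DM (5 reads) and 0.741 in T (2 reads), and was 279-fold higher in DF than in DM (119 to 861). CGI_10020518 had 145 RPKM in DF (70 reads), 0 reads in DM and 3.50 RPKM in T (2 reads). With the same floor in place of 0, CGI_10020518 was 26.6-fold higher in DF than in DM (lower limit 21.1).

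The spread of log2 differences around their median was widest between the diploid libraries. Over the 3351 genes, the median absolute deviation was 0.53 on the log2 scale between DM and DF (95% bootstrap interval over genes 0.50 to 0.55), 0.44 between T and DM (0.42 to 0.46) and 0.37 between T and DF (0.36 to 0.39). Counting error alone gave 0.11 for each pair. The order was the same with pseudocounts of 0.1 (0.55, 0.46 and 0.38) and 5 (0.46, 0.38 and 0.34). The SD, which weighs large differences more, gave another order. The SD of the log2 differences was 1.49 between T and DF, 1.38 between DM and DF and 0.81 between T and DM, and across genes Pearson's r was 0.73, 0.78 and 0.92 and Spearman's rho 0.77, 0.78 and 0.89 for these pairs. Genes are not independent replicates, so these values describe the 3 libraries only. The triploid value lay between the diploid values in 49.7% of these genes as deposited and in 43.4% after median-of-ratios scaling, where 33.3% is an equal share. Shifts shared by many genes move such shares. DF was the highest library in 58.0% of genes as deposited and 27.4% after scaling, and DM in 14.6% and 46.9%. The shares therefore do not test whether the triploid is intermediate.

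**Figure D2:**
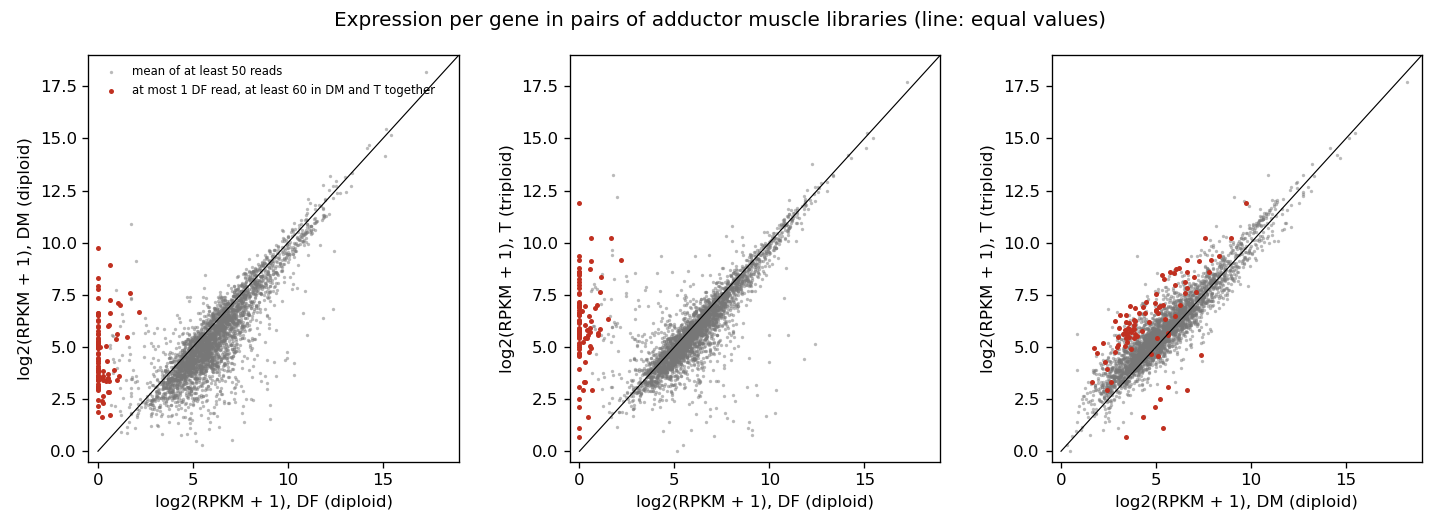
Expression of each gene, as log2(RPKM + 1), in DM against DF, T against DF and T against DM, with the line of equal values. Grey points are genes with a mean of at least 50 reads, and red points are the 92 genes with at most 1 read in DF and at least 60 in DM and T together, which lie at the left of the first 2 panels and mostly above the line (81 of 92) in the third.

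A test that takes the difference between DF and DM as the spread, and assumes that the single triploid library varies alike, was also run. limma, with 2 diploid libraries against 1 triploid library on log2(RPKM + 1), called 0 of 14402 genes at an adjusted p under 0.05, with a smallest adjusted p of 1. Because limma was run on the deposited scale only, where most genes were lower in DM than in DF, this shift is part of the spread that it used. With 2 libraries against 1, the fit also had only 1 residual degree of freedom. For both reasons limma cannot show that ploidy makes no difference. On simulated libraries of this design (14350 genes tested) it also called 0 of the 200 changed genes at an adjusted p under 0.05, including the 69 changed 8-fold.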

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

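Of the settings below, reads scaled to the total without gene length, and the counting interval together with median-of-ratios scaling, were chosen after seeing the data. Of the alternatives to the 8 counts, 49 stayed within 1.5 times the main value and 65 did not. This tally includes the rule applied to DF or DM, each diploid library alone, and limma, which count something other than the main rule does. The 8 named genes kept their direction and stayed past 2-fold in all 56 recomputations. These genes were chosen for large differences in the same data, which favours this outcome. The counting interval was not among the 56 recomputations. In each list that follows, counts are higher then lower genes, for the triploid against both diploids, T against DF, T against DM and DM against DF in turn. A pseudocount of 5 gave 439 and 86, 653 and 1241, 1477 and 241, and 345 and 2716 genes. A mean of at least 10 RPKM left 301 and 114, 460 and 1054, 1443 and 222, and 291 and 2227, since fewer genes were tested. A fold limit of 4 gave 312 and 44, 601 and 699, 884 and 169, and 332 and 1636. A fold limit of 1.5 gave 1646 and 876, 2306 and 4809, 6301 and 1430, and 1302 higher genes for the last. The counting interval of the reads left 571 and 117 for the triploid against both, 847 higher against DF, 2407 and 314 against DM, and 402 genes higher in DM than in DF. This interval with median-of-ratios scaling gave 499 and 147, 1146 and 1132 against DF, where lower genes no longer outnumbered higher ones, 1152 higher against DM, and 1323 and 1510 for DM against DF. Median-of-ratios scaling alone gave 2252 and 1448 for T against DM and 1931 and 2648 for DM against DF, trimmed mean scaling 2218 and 1505, and 2017 and 2568. Equal sums without the 20 most abundant genes gave 1123 lower in T than in DM, and 1287 and 3420 for DM against DF. For the triploid against both, no filter gave 1364 higher and a pseudocount of 0.1 gave 652 lower genes. With only DM as the diploid library there were 3656 higher and 694 lower, and with only DF 1450 and 2680, because a single comparison was used in place of both. The rule applied to DF gave 2007 higher genes, and applied to DM 195 and 2320. limma, which had a single triploid library to fit, was among the alternatives that did not stay within 1.5 times the main value. Reads scaled to the total without gene length gave all 8 counts within 1.5 times the main value. Except for the filter and the single comparisons, the cause of these differences was not tested. The median absolute deviations stayed within 1.5 times their main values in all 12 recomputations, which were made with other pseudocounts, a mean of at least 10 RPKM, and reads without gene length. The planned settings for gene lists were not run, because no identifier has a name here. Depth limits the low genes: the floor of 3 reads used for genes with 0 reads stands for 1.66 RPKM in DF, 1.46 in DM and 1.40 in T in a gene of 1 kb. No paired analysis was possible because each label has 1 library and the labels carry no replicate numbers.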

Other observations

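The tests in this part were chosen after the results were seen, except the comparison of genes detected at equal depth. Among genes with a mean of at least 50 reads, DF stood farthest apart in single genes. On the log2(RPKM + 1) scale, 49 genes were at least 16-fold lower in DF than in both other libraries, with 51 reads in DF, 12515 in DM and 55014 in T over all of them. A further 33 genes were at least 16-fold higher in DF, with 32950 reads in DF, 715 in DM and 438 in T. By the same limit, 0 genes set DM apart in either direction and 1 gene, CGI_10003417, set T apart. DM mostly lay between the other libraries: T was above DM in 45 of the 49 genes that were low in DF, and DM was above T in 28 of the 33 that were high in DF. After median-of-ratios scaling the groups held 57 and 24 genes, T was above DM in 48 of the 57, DM was above T in 22 of the 24, and 1 gene each set DM and T apart. Under the other scalings, 0 or 1 gene set DM apart and 1 or 2 genes set T apart.

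Genes near 0 in DF and abundant in the others, taken as those with at most 1 read in DF and at least 60 in DM and T together, numbered 92, against 21 with DM and 10 with T as the low library. They took 0.0019% of the reads in DF, 0.399% in DM and 1.22% in T, and 72 of them were among the genes called higher in the triploid than in both diploids, a number that the low DF reads used to choose them favour. Counting error and carry-over of T reads into DM were argued against, since simulated libraries held 0 such genes in all 100 draws, and since the DM level of the group, as a share of each library's reads, was 32.7% of the T level while CGI_10003417, abundant in T, allows at most 2.30%. Triploidy alone was argued against by the diploid library DM: of 75 genes chosen by at most 1 read in DF and at least 60 in T, with DM left free, 72 had at least 10 reads in DM (median 39), while the 212-fold level of DM over DF in the 92 genes owes its size to the choice of genes with low DF reads. A single source of RNA with a fixed make-up, in different amounts in DM and T, stays open, since the log2 ratios of T to DM over 83 of the genes had an SD of 4.79 times counting error but those of 4327 other genes in the same range of reads also had 3.01 times, and differences between the animals sampled or in the tissue taken were not tested.

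Most genes were lower in DM than in DF on the deposited scale, and the larger share of DM reads taken by the 20 most abundant genes is a candidate explanation. In the 3351 genes with a mean of at least 50 reads, leaving the 20 genes out of the totals moved the median log2 difference from -0.52 to -0.09. In 7733 genes between 3 and 30 RPKM it moved from -0.80 to -0.422 (95% bootstrap interval over genes -0.45 to -0.40), which argues against these genes as the whole cause. At 845577 reads outside the 20 genes, 15601 genes were detected in DM, 16386 in DF and 16461 in T, 4.79% fewer in DM than in DF. Lower values of many genes in DM would also lower this count, and the range of expression of the undetected genes was not examined. A less varied DM library and a difference in the muscle itself therefore both stay open.

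RPKM was lower in longer genes while reads were not higher in them. Across 3351 genes with a mean of at least 50 reads, Spearman's rho with recovered coding length was -0.71 for RPKM and -0.067 for reads, and the median reads per gene were 120.7, 103.3, 101.0 and 105.3 from the shortest to the longest of 4 equal groups. Genes are not independent replicates, and rho for reads was 0.05 among genes with a mean of at least 5 reads and -0.17 with at least 200. This is consistent with reads that come from one site or one end of each transcript, and tags and a 3' bias of other reads were not told apart. Dividing such reads by length could overstate short genes relative to long ones within a library, while the ratio of a gene's reads between libraries does not involve its length. The calls of the size rule do depend on length, since they use RPKM + 1 and a minimum mean RPKM, as does the choice of named genes.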
